A study of Homo sapiens with 8 samples.

How the data were processed

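The labels describe 8 arrays of sorted Jurkat cells, grown for 8 days (experiment 1) or 10 days (experiment 2) in control or BCAA-free medium with fetal bovine serum. Per the labels' protocols, Cy3-labelled cRNA from total RNA was hybridised to one-colour Agilent arrays. Groups, days and experiments were taken from the labels, and the arrays were numbered 1 to 4 within each group. The labels name repeats within each experiment but do not say that these came from separate cultures, so p-values that treat them as samples measure only the spread between arrays, which may be technical.

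Spots were extracted with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes. The deposited processed signal is an intensity per spot, from which, per the file headers, background and spatial trend were removed and which was not scaled between arrays. The deposited series table holds log2 values that were centred on each probe's median over the arrays, as its values show. Its columns followed the scanner values with r of at least 0.9996 and slopes of 0.999 to 1, which settles scale and direction, while the shift applied per array is not given in the sources used here. Its column medians were -0.0254, -0.0675, -0.0567 and -0.000914 for control replicates 1 to 4 and 0.0325, 0.0204, 0.0484 and 0.0515 for BCAA-free replicates 1 to 4.

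Each array had 62,976 spots, of which 60,901 were not controls and stood for 58,201 probes. Values were log2 of the processed signal minus the array's 75th percentile of it over non-control spots. Spots with outlier flags were left out, spots of a probe were averaged, and no spot was saturated. Probes well above background on at least 2 of the 8 arrays were kept, and the brightest probe stood for each gene name, which left 36,005 names. Accessions in the files were matched to RefSeq symbols, which named 31,104 probes by 22,439 symbols. Another 1,976 probes had an accession without a single match and 25,121 had none, and these kept the name in the file. The reference at hand is of another genome build than the array's, so no coordinates are given. Where dimmer probes of a named gene differed in sign or by more than 1 log2 unit, the value is given with the gene.

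Between 61.7% and 65.9% of spots on BCAA-free arrays and 72.6% to 74.3% on control arrays were well above background. The SD of negative control spots was 2.42 to 3.21 on BCAA-free and 1.33 to 1.54 on control arrays, and the lowest signal well above background was 17.7 to 22.9 and 7.1 to 8. All arrays were on 1 slide and in 1 scan, with controls in column 1 and BCAA-free arrays in column 2. A gene not well above background on any array of a group, or of 1 pair in it, has only a bound there. Its fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest spot signal well above background (-5.64 to -5.23 on BCAA-free and -6.72 to -6.49 on control arrays after scaling) and the probe's own value, all on the normalized log2 scale and with duplicates averaged first. Arrays of the bright group that were not well above background entered its mean with their measured value. Spots with outlier flags did not count for these bounds. They did count for the filter and for the numbers of genes well above background. Without them 15 of the genes would not be kept, 27,059 in place of 27,113 would be well above background on all 8 arrays, and 975 genes would be called on averaged arrays.

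Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05). The design fixed for the series fits 8 arrays as 4 means of medium and experiment, with 4 residual degrees of freedom, and takes the mean effect over experiments, the effect within each, their difference and the difference between experiments. By a robust SD, the 2 arrays of each mean differed by less than spots of 1 array (300 probes with 10 spots each, probes at least -1 on the scaled log2 axis), while the robust SD between experiments was 0.407 to 0.555. The spot SD is a plain one, and the plain SD between arrays exceeded it in 3 of 12 combinations of pair and brightness. Averaging, listed beforehand as another design, was therefore used for every statement that a gene rose, fell or changed: duplicates were averaged, and medium plus experiment were fitted on the 4 means, with 1 residual degree of freedom. This choice was made from the noise and from simulated data, not from the genes called. The fixed design is given beside it, and within an experiment values are described as higher or lower only.

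Both fits were tested on simulated data built on the real means, with noise between experiments and 200 changed genes in each of 10 draws. The simulation was revised once. Its first version, a single draw, gave a higher share of false calls for the averaged fit. It added noise between arrays on top of a spread between experiments that already held it, and the revision removed this, smoothed the noise between arrays over brightness and used more draws. The share of false calls stayed far above the nominal 0.05. Alternative prior variances were compared on the revised simulation before the averaged fit was kept as first listed. For the main comparison with 35,916 genes, the averaged fit recovered 4.2% of genes changed by 1 log2 unit and 73.6% of those changed by 2, and a mean of 28.8% of its 113.3 calls were unchanged genes. Limited to 27,060 genes well above background on all 8 arrays, 15% of its calls were unchanged genes. A prior variance that follows the spread between duplicates gave 18.1%. The fit of 8 separate arrays called a mean of 18,565 genes, of which 99% were unchanged. The simulation gave each medium and experiment its own random shift per gene and counted it as no change. A fit that measures only the spread between arrays must then call many unchanged genes, so this share was largely fixed in advance. Camera on averaged values called a list of 30 genes shifted by 1 log2 unit in 10 of 10 draws and 0 of 400 unshifted lists. The simulated noise was drawn separately for each gene, so this cannot test lists whose genes vary together. On the real averaged values, the estimated correlation within a list ranged from -0.11 (PRC2 subunits) to 0.9 (histone genes).

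The 41 gene lists, the rule for named genes and all settings other than those named as added were fixed before the data were examined. Of 1,032 list entries 981 were measured. The lists cover BCAA catabolism, amino acid transport, ATF4 targets, serine and one-carbon enzymes, tRNA synthetases, mTORC1, PRC1, PRC2 and its targets, dioxygenases, central and lipid metabolism, lysosomes, stress responses, cell cycle, histones, ribosomes, apoptosis, T-cell and leukaemia programmes, interferon, and markers of B, myeloid, erythroid and stromal cells. Lists were tested with camera on the 8 arrays (preset correlation of 0.01), which called 22 of 41. With an estimated correlation 3 were called (histones, cholesterol genes, immediate early genes). Fry, which asks whether a list's genes move on balance one way, called 36 on the 8 arrays. The rule names the 12 largest rises and 12 largest falls of the main comparison with a symbol, well above background on all 4 arrays of the higher group and on 1 side in both experiments. For the other comparisons it names the 4 largest either way, in each discussed list up to 4 members with the smallest p in the fit of 8 arrays, and 23 genes in any case.

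Replicate numbers were checked for pairing across media. The deviations of same-numbered arrays from their group means correlated at 0.42, 0.42, 0.41 and 0.44 across genes, and the other number of the same experiment gave 0.37 to 0.44. Arrays of the same experiment share its difference from the group mean, so this check cannot show pairing by number. The replicate block takes the numbers to pair the arrays, which is an assumption. Alternatives were normexp background (offset 50, on the spots' median signal because the mean signal is not analysed here), quantile normalization, median scaling, the deposited log2 table, other filters and probe rules, other priors and thresholds, other designs with and without blocks, and leaving out each array. A slide block was not run because there is 1 slide. Added after the data were seen were the prior that follows the spread between duplicates, the common floor (-5.23), the filter without spots with outlier flags, the fits of 1 experiment alone, the count without histone genes and small non-coding RNAs, set tests on averaged values and the count of genes at least 2-fold away in both experiments. Values of 6 genes of these lists are not reported here, while counts, medians and tests of the lists include them. No other data were left out.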

Results

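Gene expression was measured in Jurkat cells, an established line of human T-cell acute lymphoblastic leukaemia, grown with or without the branched-chain amino acids (BCAA) leucine, isoleucine and valine and purified by cell sorting before RNA extraction. The series holds 8 one-colour Agilent arrays, 4 from control medium and 4 from BCAA-free medium. Experiment 1 lasted 8 days and experiment 2 lasted 10 days, and each gave 2 control and 2 BCAA-free arrays. For most probes both arrays of such a pair differed by less than the noise between spots on a single array. Over 12 combinations of pair and brightness, the robust SD between arrays was 0.034 to 0.066 and the SD between repeated spots of 1 probe on 1 array 0.06 to 0.083. The plain SD between arrays, which outlying probes enlarge, was 0.041 to 0.094 and exceeded the spot SD in 3 of the 12. The pairs were averaged and counted as 1 sample, so that n = 2 experiments per group. Between 35,072 and 37,624 probes were well above background on each BCAA-free array, against 41,680 to 42,698 on each control array. All controls lay in 1 column of the slide and all BCAA-free arrays in the other, so slide position and medium cannot be told apart, and the number of arrays limits the precision.

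The main comparison asks how gene expression differed between cells without and with BCAA over both experiments. Among genes named by the rule and well above background in both groups, the largest rise was that of PROK2, which encodes a secreted prokineticin. It rose 46.6-fold (log2 5.54 ± 0.40 SE, n = 2 experiments per group, limma adjusted p = 5.63e-07). RGS16, a regulator of G-protein signalling, rose 26.8-fold (log2 4.74 ± 0.42 SE, adjusted p = 2.55e-06), and the Wnt pathway gene PYGO1 rose 17.4-fold (log2 4.12 ± 0.44 SE, adjusted p = 1.51e-05). With the same limits, immediate early transcription factors had the largest falls: FOS was 56.6-fold lower (log2 -5.82 ± 0.46 SE, adjusted p = 7.98e-07) and EGR1 27.5-fold lower (log2 -4.78 ± 0.43 SE, adjusted p = 2.55e-06). Each SE is limma's, which leans on the spread over all genes. It therefore does not show how far a gene's 2 experiments lay apart: the effect on FOS was -4.65 at 8 days and -7 at 10 days. The inducible HSP70 gene HSPA1A was not well above background on any BCAA-free array and fell at least 5.11-fold (adjusted p = 1.54e-05). Among genes well above background on all 8 arrays, 562 of 27,113 were at least 2-fold away from the controls in the same direction in both experiments (350 higher, 212 lower), and 99 were so in opposite directions. This count was chosen after the data were seen, and with normexp background it was 271 (138 higher, 133 lower). Lists that long would share 73 higher and 28 lower genes if independent, and the experiments have no control array in common. Of the genes in opposite directions, 89 were higher at 8 and lower at 10 days and 10 the reverse. The number expected for these was not computed. Both experiments share the placement of media on the slide, so the overlap cannot tell medium and slide position apart.

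The other rises named by the fixed rule were those of FOXN4 (15.8-fold), NLGN4X (14.1-fold), RASSF8-AS1 (13.8-fold), RASEF (10.8-fold), PIERCE2 (at least 8.80-fold), ZNF697 (at least 5.97-fold) and CCND2, which encodes the G1 cyclin D2 (log2 3.31 ± 0.38 SE, 9.95-fold). FOXN4 and RASSF8-AS1 were well above background on 3 of the 4 control arrays and PIERCE2 and ZNF697 on 2, with no 10-day control array among them, and a second, dimmer probe of ZNF697 gave a log2 difference of -0.63. CXXC4 and the homeobox gene SIX4 were not well above background on any control array, and rose at least 4.86-fold and at least 6.55-fold (adjusted p = 1.01e-05 and 2.19e-05). The interleukin-22 receptor subunit gene IL22RA1, the hepatic lipase gene LIPC, the inflammatory caspase gene CASP1 and KHDC3L were not well above background on any BCAA-free array. They fell at least 4.10-fold, at least 13.7-fold, at least 4.21-fold and at least 1.81-fold (adjusted p = 2.72e-06, 3.12e-06, 1.54e-05 and 6.85e-05). FAM30A fell 13.6-fold, DEPP1 11.6-fold, the cytokine gene TNF 9.96-fold, RAB33A 8.90-fold and the prolactin gene PRL at least 5.86-fold, while DEPP1 and PRL were well above background on 2 of the 4 BCAA-free arrays. The rule requires each of these 24 genes to lie on the same side of the controls in both experiments. PIERCE2, PRL and RAB33A were no longer called without BCAA-free replicate 1 (adjusted p = 0.0523, 0.0665 and 0.0665) or with the replicate block (0.0643, 0.0551 and 0.0575).

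**Figure D1:**
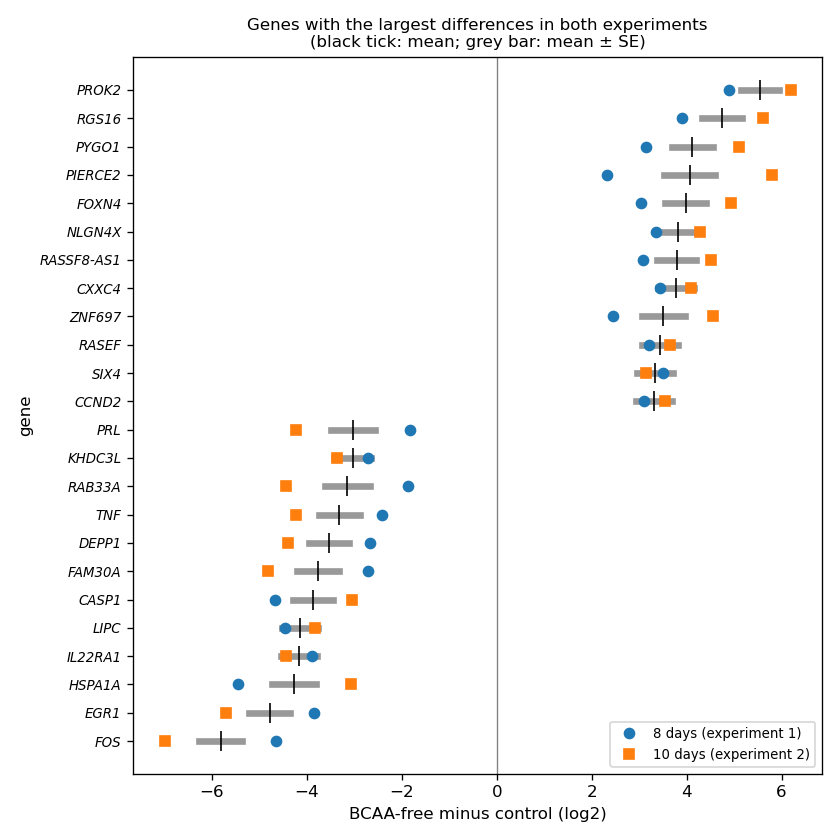
Log2 difference between BCAA-free and control cells for the 24 genes named by the rule of the main comparison, with circles for the 8-day experiment, squares for the 10-day experiment, a tick for their mean and a grey bar for 1 limma SE on either side. They range from FOS (mean -5.82) to PROK2 (mean 5.54), and the rule requires 1 side of 0 in both experiments; CXXC4, SIX4, HSPA1A, IL22RA1, LIPC, CASP1 and KHDC3L are drawn at their measured differences, although 1 group was not well above background, and so are PIERCE2, ZNF697 and PRL, for which 1 pair of arrays was not.

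On the averaged arrays, limma called 979 of 36,005 genes, 645 higher and 334 lower, and all 979 lay in the same direction in both experiments. The difference between the experiments' effects is the residual of this fit, so a gene with opposite signs could hardly pass. The shared direction is therefore largely fixed by the test. Of the 979, 319 higher and 152 lower genes were well above background on all 8 arrays, while genes measured on exactly 2 arrays gave 163 higher and 5 lower calls. Probes well above background on no array were 1.02 log2 units higher on the BCAA-free side of the slide. This fit has 1 residual degree of freedom and uses prior degrees of freedom estimated over all genes, 18.7 here. Under median scaling the prior was 5.4 and 103 genes were called (81 higher, 22 lower). This ended the call of 38 of the 54 genes whose calls in the main comparison were followed here. PROK2, RGS16, FOS, EGR1, CCND2, NLGN4X, RASSF8-AS1, RASEF, CXXC4, SIX4, IL22RA1, LIPC, CASP1, KHDC3L, DEPP1 and HOXB9 stayed called. Under a common floor for all values, normexp background, no filter on dim probes or quantile normalization it was 0.7 to 4.3 and limma called 0 (2,639, 2,833, 9,157 and 3,529 at an unadjusted p under 0.05), so that all 54 lost their call, without a change of direction. The deposited table ended 9 of the 54 calls (BMP2, FASN, GATA6, HERPUD1, IKZF3, MEF2C, STC2, TNFAIP2 and VWF) and the mean of a gene's probes 6 (FASN, GATA6, SREBF1, STC2, VWF and ZNF697). Leaving out control replicate 2, control replicate 4, BCAA-free replicate 1, 2 or 3 ended the call of 19, 11, 29, 1 and 23 of the 54, and in what follows the array with the highest resulting p is named. The count was 420 without control replicate 2, 609 without control replicate 4, 220 without BCAA-free replicate 1, 302 without BCAA-free replicate 3 and 1,474 without BCAA-free replicate 4. With the 8 arrays as separate samples, the design fixed for the series, 17,854 genes were called (8,056 higher, 9,798 lower), a count that measures the spread between paired arrays. It was 1,912 (934 higher, 978 lower) with the replicate number as a block and 2 (0 higher, 2 lower; 2,158 at an unadjusted p under 0.05) with the pair of arrays as a random block. On those separate arrays with the replicate block, 33 named genes that did not pass on averaged arrays were called (adjusted p = 0.0151 to 0.0498), among them RAG1 (0.0151), ACSL3 and GADD45A (0.0166 each), CCNG2 (0.0172), DDIT3 (0.0176), HOXA7 (0.02), CD2 (0.0203), HSPA1B (0.023), GATA3 (0.0247), MCM2 (0.0248), KDM6B (0.0283), BCAT2 (0.0284), GINS2, RFC5 and IDH1 (0.0297 each), KLF2 (0.0312), BAG3 (0.0336), UVRAG (0.0339), DEPTOR (0.034), BIK (0.0343), CD1B (0.0346), LCP2 (0.0352), PFKP (0.0357), TAP1 and BID (0.0366 each), PDK1 (0.0369), PCGF3 (0.0407), DDIT4 (0.0412), PHLDA3 (0.0462), IL7R (0.0484) and CDT1 (0.0498). The block fit counts paired arrays as separate samples, so its p-values rest on more samples than the 2 experiments per group. Those 33 genes are therefore not counted as having risen or fallen. With 8 separate arrays and no block, 818 of the 979 were among the 17,854 genes.

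Of 41 gene lists, camera on the 8 arrays called 22. With duplicates averaged it called 14, and with an estimated correlation as well 0 of 41 (the lowest adjusted p was 0.688). Lists that lost their call on averaged values were amino acid transporters (adjusted p = 0.0646), HIF1 hypoxia targets (0.0687), glycolysis enzymes, TCA cycle enzymes, NF-kB targets, MYC and ribosome biogenesis genes (0.0901 each), myeloid markers (0.138), PRC2 subunits (0.194) and G2/M genes (0.321). On the 8 arrays fry called 36 lists, which are the 22 and BCAA catabolism enzymes, mTORC1 genes, PRC1 subunits, textbook PRC2 target genes, aminoacyl-tRNA synthetases, serine enzymes, endoplasmic reticulum chaperones, oxidative phosphorylation subunits, NRF2 targets, p53 targets, CDK inhibitors, NOTCH targets, T-cell leukaemia transcription factors and B cell markers, and with duplicates averaged it called 0. Camera called textbook PRC2 target genes on averaged values (0.0354) and with the replicate block but not on the 8 separate arrays. The camera p-values below are from the 8 arrays, and so measure the spread between paired arrays.

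T-cell activation and immediate early genes were lower as a group. Of 23 measured members, 0 rose, 10 fell and 13 did not pass the test, and 15 fell when adjusted over the list alone. The median log2 difference was -1.32, with -1.09 in the 8-day and -1.70 in the 10-day experiment. Beside FOS, EGR1 and TNF, falls were measured for DUSP2, a phosphatase gene (log2 -2.17 ± 0.42 SE, 4.52-fold), for the early activation marker CD69 (log2 -2.02 ± 0.40 SE, 4.07-fold) and for IER3 (log2 -1.86 ± 0.38 SE, 3.63-fold). The list was called by camera (adjusted p = 1.96e-09, and adjusted p = 0.0286 with an estimated correlation). On averaged values with an estimated correlation, camera did not call it (adjusted p = 0.688). Without BCAA-free replicate 1, DUSP2 (adjusted p = 0.101), CD69 (adjusted p = 0.0774) and IER3 (adjusted p = 0.0669) were not called, nor was DUSP2 with the replicate block (0.052).

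Genes of cholesterol synthesis and uptake were also lower. Of 24 measured members, 0 rose, 8 fell and 16 did not pass, and 18 fell when adjusted over the list alone (camera adjusted p = 4.35e-10, and adjusted p = 0.0286 with an estimated correlation). Camera did not call the list on averaged values with an estimated correlation (adjusted p = 0.688). HMGCS1, which encodes the cytosolic HMG-CoA synthase, fell by 2.28 ± 0.43 SE on the log2 scale and INSIG1, a regulator of sterol sensing, by 1.87 ± 0.39 SE. LSS and FDFT1, enzymes of the pathway, differed by log2 -1.63 and -1.46 without passing the test. The list's median was -0.31 at 8 days and -2.05 at 10 days. In fatty acid synthesis 0 of 12 genes rose, 3 fell and 9 did not pass, with 7 falls adjusted over the list alone. The transcription factor gene SREBF1 (log2 -1.84 ± 0.39 SE), the desaturase gene FADS2 (log2 -2.09 ± 0.44 SE) and the fatty acid synthase gene FASN (log2 -1.58 ± 0.41 SE) fell, and ACSL3 differed by -1.09. Camera called this list lower (adjusted p = 2.59e-07, but adjusted p = 0.113 with an estimated correlation). A dimmer probe of SREBF1 gave -0.58, and without BCAA-free replicate 1 HMGCS1 (adjusted p = 0.0931), INSIG1 (0.099), SREBF1 (0.0933), FADS2 (0.144) and FASN (0.2) were not called. With the replicate block HMGCS1 (0.0526), FADS2 (0.0834) and FASN (0.0762) were not called.

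Targets of ATF4, the transcription factor of the amino acid response, were higher as a list. Of 25 measured members 3 rose, 0 fell and 22 did not pass, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.49e-06, but adjusted p = 0.115 with an estimated correlation). ATF5 rose 6.53-fold (log2 2.71 ± 0.38 SE, adjusted p = 0.000209) and HERPUD1, a gene of endoplasmic reticulum protein degradation, rose 2.77-fold. The third was STC2 (3.01-fold), named after its value was seen. TRIB3 differed by log2 1.48 (adjusted p = 0.0516), DDIT3 by 1.01 and DDIT4 by -1.11. ATF4 mRNA itself differed by 0.08, SESN2 by 0.79 and the asparagine synthetase gene ASNS by 0.73. The list's median was 0.89 at 8 days and 0.18 at 10 days, and in control cells the list lay 1.42 higher at 10 than at 8 days. Among amino acid transporters 0 of 21 rose or fell, with 3 higher adjusted over the list alone (median 0.24, camera adjusted p = 0.0082, but adjusted p = 0.135 with an estimated correlation and 0.0583 with the replicate block). SLC6A9 differed by 1.54, SLC43A2 by 1.22, SLC38A9 by 0.89, the cystine transporter gene SLC7A11 by 0.83, and SLC7A5 and SLC3A2, which encode the LAT1 transporter's subunits, by 0.33 each. HERPUD1 was not called without BCAA-free replicate 1 (adjusted p = 0.133) and STC2 not without BCAA-free replicate 3 (adjusted p = 0.209) or with the replicate block (0.0848).

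The list of BCAA catabolism enzymes was not called by camera. None of 25 measured members rose or fell, also when adjusted over the list alone (0 called), and the median was -0.05 (camera adjusted p = 0.96, but fry adjusted p = 0.00391 on the 8 arrays and 0.937 on averaged values). BCAT1, the cytosolic transaminase that acts first on BCAA, differed by log2 0.75 ± 0.39 SE and its mitochondrial counterpart BCAT2 by -0.80 ± 0.38 SE. The other enzymes with fixed names were closer to 0, with BCKDHA at -0.28, BCKDHB at 0.11, DBT at -0.01 and the kinase gene BCKDK at -0.05, and AUH (-0.64) and ACAD8 (-0.60) had the smallest p after BCAT1 and BCAT2. None of the 31 mTORC1 nutrient sensing genes was called, over all genes or adjusted over the list alone (median -0.09, camera adjusted p = 0.629, but fry adjusted p = 0.0137 on the 8 arrays and 0.954 on averaged values). MLST8 differed by 0.36, NPRL3 by -0.35 and DEPTOR by 0.79.

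Subunits of PRC2, the complex that methylates histone H3 at lysine K27, were lower as a list, with 0 of 10 called over all genes or adjusted over the list alone (median -0.33, camera adjusted p = 0.0054, but adjusted p = 0.11 with an estimated correlation). EZH2 differed by log2 -0.39 ± 0.38 SE, RBBP7 by -0.47, PHF19 by -0.52, MTF2 by -0.46, PHF1 by -0.49 and SUZ12 by -0.12, and EED was not analysed here. Of 46 textbook PRC2 target genes 5 rose and 1 fell, both over all genes and adjusted over the list alone, and 40 did not pass. The homeobox genes HOXB9 (log2 2.74 ± 0.38 SE) and LHX2 (log2 2.57 ± 0.45 SE) rose and WT1 fell (log2 -1.99 ± 0.38 SE), and HOXA7 differed by 0.98. GATA6 (1.73, well above background on 3 control arrays), BMP2 and HOXA11 were the other risers. GATA6 and HOXA11 were named after their values were seen, BMP2 by the rule for 10 days, and BMP2 and HOXA11 were well above background on 2 of 4 BCAA-free arrays and on no control array (at least 4.05-fold and at least 2.14-fold). For BMP2 these were the 10-day arrays (normalized log2 -1.87 and -1.79), against -7.02 and -7.61 on the 8-day BCAA-free arrays. Its rise thus rests on 1 culture. For HOXA11, BCAA-free replicates 2 and 4 (-6.37 and -5.62) were not well above background and entered the bound as measured. Probes well above background on no array lay a median of 1.02 log2 units higher on the BCAA-free side. An offset of that size was not taken out of these bounds, so a technical origin of the rise of HOXA11 stays open. The list's median was 0.10 and camera did not call it (adjusted p = 0.081; 0.0478 with the replicate block). Of 15 PRC1 subunits and 27 dioxygenases that use 2-oxoglutarate none was called, over all genes or adjusted over the list alone. Their medians were 0.06 and 0.00 (camera adjusted p = 0.56 and 0.969), with PCGF3 at -0.72, RNF2 at 0.62 (-0.15 on a dimmer probe), BMI1 at 0.40 and CBX2 at 0.33 (-0.18 on a dimmer probe), and KDM6B at 0.78, TET1 at -0.57, PHF8 at 0.53 and KDM4B at -0.46 (0.12 on a dimmer probe). Without BCAA-free replicate 1, LHX2 (adjusted p = 0.0902), WT1 (0.0501), GATA6 (0.315), BMP2 (0.29) and HOXA11 (0.111) were not called, nor were LHX2 (0.0656), GATA6 (0.144) and BMP2 (0.192) with the replicate block.

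Of 28 transcription factors of T-cell leukaemia 4 rose, 0 fell and 24 did not pass, the same numbers as when adjusted over the list alone, while the list had a median of 0.00 and a mean of 0.15 (camera adjusted p = 0.96). LMO2, an oncogene of T-cell leukaemia, rose 5.44-fold (log2 2.44 ± 0.39 SE) and the Ikaros family gene IKZF3 3.19-fold (log2 1.67 ± 0.41 SE). HHEX (at least 3.08-fold) and MEF2C, named after their values were seen, were well above background on 1 control array each and on 3 and 1 BCAA-free arrays. TAL1 differed by -0.58 and GATA3 by -0.84. Among 19 haematopoietic stem and progenitor genes 2 rose, 0 fell and 17 did not pass, with 3 higher adjusted over the list alone (median 0.40, camera adjusted p = 0.0296, but adjusted p = 0.126 with an estimated correlation). These were LMO2 and MYCN (3.99-fold), while HLF differed by 1.57. T-cell receptor and T-lineage genes were lower as a list (median -0.32, camera adjusted p = 0.00178, but adjusted p = 0.0727 with an estimated correlation), with 0 of 35 rising, 1 falling and 34 not passing, and 1 fall adjusted over the list alone. The fall was that of CD1D (log2 -1.62 ± 0.38 SE), named after its value was seen, and RAG1 differed by 1.25, CD2 by -0.95, CD1B by -1.13 and LCP2 by -0.68. None of the 18 NOTCH pathway targets was called, over all genes or adjusted over the list alone (median -0.21, camera adjusted p = 0.463), with FJX1 at 1.1, DTX1 at -1.06, IL7R at -0.74 and NOTCH3 at -0.81. Without BCAA-free replicate 1, IKZF3 (adjusted p = 0.157), HHEX (0.187), MYCN (0.0523) and CD1D (0.141) were not called, and MEF2C was not without BCAA-free replicate 3 (0.544), in the fixed design of 8 separate arrays (0.106) or with the prior that follows the spread between duplicates (0.193). With the replicate block IKZF3 (0.0614), HHEX (0.0932) and MEF2C (0.296) were not called.

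Interferon-stimulated genes were lower as a list, with 0 of 32 rising, 2 falling and 30 not passing, and 2 falls adjusted over the list alone (median -0.36, camera adjusted p = 0.000107, but adjusted p = 0.0727 with an estimated correlation). The guanylate-binding protein gene GBP1 fell 5.10-fold (log2 -2.35 ± 0.42 SE) and OAS1, named after its value was seen and well above background on 2 of 4 BCAA-free arrays, at least 3.34-fold, while IFIT3 differed by -1.15 and PSMB9 by -0.73. None of 15 MHC class I and II genes was called, over all genes or adjusted over the list alone (median -0.49, camera adjusted p = 0.000368, but adjusted p = 0.0727 with an estimated correlation), with TAP1 at -0.65, B2M at -0.54 and TAP2 at -0.59 (0.08 on a dimmer probe). Of 15 NF-kB targets 0 rose, 1 fell and 14 did not pass, with 1 fall adjusted over the list alone (median -0.24, camera adjusted p = 0.0125, but adjusted p = 0.113 with an estimated correlation and 0.0514 with the replicate block). TNFAIP2 fell by 1.59 ± 0.39 SE on the log2 scale, and CD82, TRAF1 and NFKBIA differed by -0.76, -0.60 and -0.34. Without BCAA-free replicate 1, GBP1 (adjusted p = 0.071) and OAS1 (0.0656) were not called, and TNFAIP2 was not without BCAA-free replicate 3 (0.132).

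Camera called no list of markers of other cell types higher. Of 14 myeloid markers 0 were called, over all genes or adjusted over the list alone (median -0.33, camera adjusted p = 0.0437, but adjusted p = 0.431 with an estimated correlation, 0.0666 without control replicate 4, 0.0662 without BCAA-free replicate 2 and 0.0504 without BCAA-free replicate 4), with CEBPA at 0.83, SPI1 at -0.81, FCER1G at -0.37 and PRTN3 at -0.45. None of 9 B cell markers and none of 15 erythroid and megakaryocyte markers was called, over all genes or adjusted over the list alone. Their medians were -0.13 and -0.08 (camera adjusted p = 0.523 and 0.692), with BLNK at -0.25, MS4A1 at -0.37 and CD79A at -0.13, and KLF1 at -0.34, ALAS2 at 0.16 and ITGA2B at -0.38. Of 13 stromal, endothelial and epithelial markers 1 rose, 0 fell and 12 did not pass, with 1 rise adjusted over the list alone (median -0.26, camera adjusted p = 0.96). This was VWF (log2 1.74 ± 0.46 SE), whose dimmer probe gave 0.07 and which was not called without BCAA-free replicate 1 (adjusted p = 0.273) or with the replicate block (0.137), and PECAM1, KRT18 and CDH5 differed by -0.71, 0.41 and -0.41.

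No member of the cell-cycle and metabolic lists in this paragraph rose or fell, over all genes or adjusted over the list alone. G1/S and DNA replication genes (39 measured) had a median of -0.24 (camera adjusted p = 5.36e-05, but adjusted p = 0.0727 with an estimated correlation), with MCM2 at -0.79, CDT1 at -0.80, and GINS2 and RFC5 at -0.72 each. G2/M and mitosis genes (34) had a median of -0.20 (adjusted p = 0.0283, but adjusted p = 0.115 with an estimated correlation, 0.25 with the replicate block, 0.157 after quantile normalization and 0.0543 without BCAA-free replicate 1), with PTTG1 at -0.63 and HMMR at 0.50. TCA cycle enzymes (24) had a median of -0.25 (adjusted p = 8.64e-05, but adjusted p = 0.0706 with an estimated correlation), with IDH1 at -0.75 and IDH2 at -0.55. Glycolysis enzymes (20) had a median of -0.28 (adjusted p = 0.00103, but adjusted p = 0.0727 with an estimated correlation), with ALDOC at -1.80 and PFKP at -0.64, and HIF1 hypoxia targets (18) a median of -0.35 (adjusted p = 0.0079, but adjusted p = 0.11 with an estimated correlation), with PDK1 at -0.75, BHLHE40 at -1.31 and VEGFA at 0.95. MYC and ribosome biogenesis genes (40) had a median of 0.13 (adjusted p = 0.000171, but adjusted p = 0.0706 with an estimated correlation and 0.0583 with the replicate block). Replication-dependent histone genes (39) had a median of 0.40 (adjusted p = 1.25e-10, and adjusted p = 0.0286 with an estimated correlation), with H2AC8 at 1.12 and H4C4 at 0.74. On averaged values with an estimated correlation, camera did not call the histone genes (adjusted p = 0.928). MYC differed by 0.49, with RRS1 at 0.90 and NOP16 at 0.64. Of the 40 MYC and ribosome biogenesis genes, 6 were higher and 4 lower in both experiments.

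Of 14 heat shock protein genes 0 rose, 1 fell and 13 did not pass, with 1 fall adjusted over the list alone (median -0.43, camera adjusted p = 0.000418, but adjusted p = 0.113 with an estimated correlation). The fall was that of HSPA1A, and HSPA1B differed by -1.03, BAG3 by -0.69 and HSPA8 by -0.58. Metallothioneins (9 measured, 0 called over all genes, 1 fall adjusted over the list alone) had a median of -0.39 (camera adjusted p = 0.0432, but adjusted p = 0.363 with an estimated correlation, 0.0534 after quantile normalization and 0.0585 without control replicate 3), with MT1E at -0.85 and MT2A at -0.89. In the BCL2 family, regulators of apoptosis, 2 of 16 genes rose, 0 fell and 14 did not pass, with 2 rises adjusted over the list alone (median 0.21, camera adjusted p = 0.0471, but adjusted p = 0.294 with an estimated correlation). The pro-apoptotic gene BBC3 rose 3.74-fold (log2 1.90 ± 0.41 SE) and HRK, named after its value was seen, 6.58-fold, while BCL2A1 differed by 0.90 (-0.95 on a dimmer probe), BID by -0.67 and BIK by 0.67. BBC3 was not called without BCAA-free replicate 1 (adjusted p = 0.117) or with the replicate block (0.0505), and the list was not called without control replicate 3 (0.0528), control replicate 4 (0.0656), BCAA-free replicate 2 (0.0566) or BCAA-free replicate 3 (0.0919). Of 24 p53 targets BBC3 was the 1 that rose and 0 fell, with 1 rise and 1 fall adjusted over the list alone (median 0.09, camera adjusted p = 0.144), and GADD45A differed by -1.34, PHLDA3 by 0.84 and AEN by 0.74. None of 21 CDK inhibitors and quiescence genes was called, over all genes or adjusted over the list alone (median -0.29, camera adjusted p = 0.081; 0.0408 with the replicate block). CCNG2 differed by -1.30 (-0.23 and -0.41 on dimmer probes), CDKN2D by -0.82, KLF2 by -0.76, TXNIP by 0.74, CDKN1B by -0.12 and CDKN1C by -0.53. CDKN1A was not well above background on any BCAA-free array and did not pass the test (limma adjusted p = 0.79), so no direction is given.

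The remaining lists were not called by camera, and their genes did not pass the test over all genes or adjusted over the list alone, except HERPUD1. Of 21 genes for endoplasmic reticulum chaperones and the unfolded protein response HERPUD1 was the 1 that rose and 0 fell, with 1 rise adjusted over the list alone (median 0.07, adjusted p = 0.326), and SEL1L differed by 1.01, HSPA5 by -0.72 and PDIA6 by -0.62. Cytosolic aminoacyl-tRNA synthetases (19) had a median of 0.14 (adjusted p = 0.0702; 0.0222 after quantile normalization), with LARS1 at 0.85. Oxidative phosphorylation subunits (45) had a median of -0.12 (adjusted p = 0.103), with ATP5F1C at -0.39 and NDUFB10 at 0.40, and lysosome and autophagy genes (36) a median of 0.09 (adjusted p = 0.612), with UVRAG at -0.67. For NRF2 oxidative stress targets (17) the median was -0.01, the mean 0.04 and the test's direction up (adjusted p = 0.797), with TXNRD1 at 0.55 and PRDX1 at -0.52. For cytosolic ribosomal proteins (56) the median was -0.03 and the mean -0.02 while the test's direction was up (adjusted p = 0.969; 0.028 after quantile normalization), with RPS15 at -0.45. Enzymes of serine, proline and one-carbon metabolism (17) had a median of -0.01 (0.03 after quantile normalization, adjusted p = 0.96), with SHMT1 at -0.39 and PSAT1 at 0.32.

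**Figure D2:**
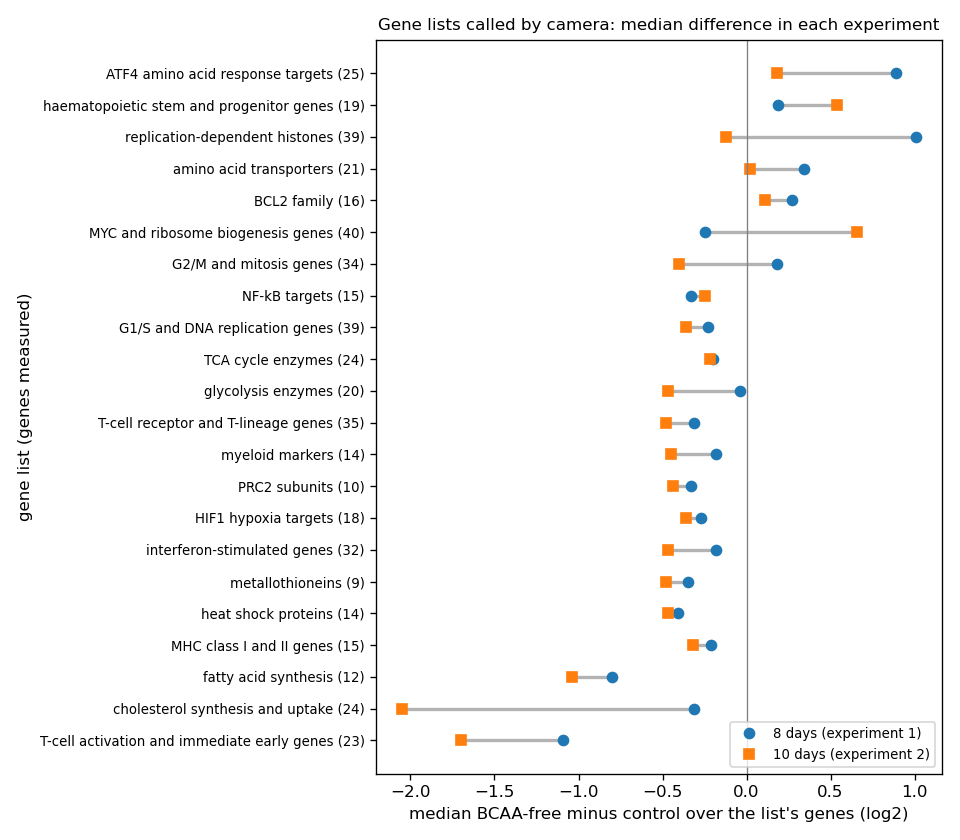
Median log2 difference between BCAA-free and control cells over the measured genes of the 22 lists that camera called, with circles for the 8-day and squares for the 10-day experiment and the number of measured genes in parentheses. Immediate early genes lie below 0 in both experiments (-1.09 and -1.70), while histone genes (1.01 and -0.12) and MYC and ribosome biogenesis genes (-0.25 and 0.66) lie on opposite sides of 0.

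Within the 8-day experiment, which held 1 averaged sample per medium, WTAPP1, GALR1, L1TD1 and NPSR1-AS1 were the genes named by the rule as higher and were not well above background in control cells. They were at least 28.4-fold, at least 14.3-fold, at least 22.6-fold and at least 12.6-fold higher in BCAA-free cells. Without BCAA-free replicate 1 the values were at least 18.2-fold for WTAPP1 and at least 8.30-fold for GALR1, without BCAA-free replicate 2 at least 44.5-fold and at least 24.5-fold, and a second probe of NPSR1-AS1 differed over both experiments by log2 -0.92. FOS was 25.1-fold lower, HSPA1A at least 11.8-fold, CASP1 at least 7.96-fold and LIPC at least 16.6-fold. BBC3 was 6.09-fold and ASNS 3.07-fold higher. Against the spread between paired arrays limma called 14,744 genes, 7,532 higher and 7,212 lower (4,889 and 10,228 with median scaling), which compares these cultures and not the media, and 2,398 of them differed at least 2-fold.

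Within the 10-day experiment, BMP2, SNORD114-14 and LHX4 were not well above background in control cells. BMP2 and SNORD114-14 were at least 25.6-fold and at least 19.4-fold higher in BCAA-free cells. LHX4 was at least 4.33-fold higher without BCAA-free replicate 4 and at least 77.7-fold without BCAA-free replicate 3, and was not called with a common floor (adjusted p = 0.15), with normexp background (0.0594) or without control replicate 3 (0.0516) or 4 (0.0539). PROK2 was 73-fold higher. FOS was 128-fold, EGR1 52.5-fold, FAM30A 28-fold and RAB33A 21.7-fold lower. The sterol genes HMGCS1 and LSS were 8.92-fold and 8.10-fold lower, against 2.66-fold and 1.18-fold at 8 days. Limma called 19,405 genes against the spread between paired arrays, 8,188 higher and 11,217 lower, and 4,659 of them differed at least 2-fold.

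The effect of BCAA-free medium differed between the experiments for many genes and lists. CHAC1, an ATF4 target that degrades glutathione, was 4.93-fold higher at 8 days and 5.37-fold lower at 10 days (difference of the effects, log2 -4.73), and SNORA2C (-5.12), RARB and CRYBA1 differed in the same direction. DACT1, SCN2B, DAPL1 and NOX4 differed the other way. For the 6 genes without a value, at least 1 of the 4 pairs of arrays was not well above background, and with a common floor RARB (adjusted p = 0.205), DAPL1 (0.159) and CRYBA1 (0.0972) were not called. DAPL1 was also not called without control replicate 1 (0.059), control replicate 2 (0.0546) or BCAA-free replicate 1 (0.0547), and RARB not with the mean of its probes (0.0859). A dimmer probe of RARB was 4.42 higher over both experiments where the named one was 0.45 higher. MYC was 1.28-fold lower at 8 days and 2.54-fold higher at 10 days. MYC and ribosome biogenesis genes had median effects of -0.25 and 0.66 (camera on the difference, adjusted p = 5.93e-15, and adjusted p = 0.024 with an estimated correlation), histone genes of 1.01 and -0.12 (adjusted p = 4.14e-11, and 0.024 with an estimated correlation) and cholesterol genes of -0.31 and -2.05 (adjusted p = 2.94e-09, and 0.0297 with an estimated correlation). Across the 27,113 genes well above background on all 8 arrays, which are not independent replicates, the effects correlated with Pearson's r of 0.27 and Spearman's rho of 0.14, and 51.5% had the same sign. Limma called the difference for 17,216 genes, 7,643 higher and 9,573 lower (9,393 and 6,477 with median scaling), against the spread between paired arrays, so that day of culture, experiment and culture-to-culture variation cannot be told apart.

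The experiments also differed within each medium, in the 10-day against the 8-day cultures. The ribosomal RNA genes RNA5-8SN5 and RNA18SN5 were higher in experiment 2 by log2 5.14 and 3.19, and so were VEGFA, an angiogenic growth factor gene (3.20), and ZNF606-AS1. The chemokine receptor gene CXCR3 (-3.44, with a BCAA-free difference of -1.59 that was -0.15 on a dimmer probe), FAM177B (-3.25), CD93 and the chemokine gene CCL1 (-3.00) were lower. ZNF606-AS1 was not well above background in 8-day control cells, nor CD93 on any 10-day array, so no size is given. In control cells, histone genes were higher at 10 days by a median of 1.99 and ATF4 targets by 1.42, while MYC and ribosome biogenesis genes differed by -1.27. In BCAA-free cells these medians were 0.48, 0.52 and -0.35. On the averaged arrays limma called 1,344 genes (904 higher, 440 lower), but 0 with normexp background, quantile normalization, median scaling, no filter on dim probes or a common floor (6,745, 5,522, 6,009, 5,376 and 4,862 at an unadjusted p under 0.05). It called 28 without control replicate 2, 2,246 without control replicate 3, 410 without control replicate 4, 1 without BCAA-free replicate 1, 1 without BCAA-free replicate 3 and 2,032 without BCAA-free replicate 4. With 8 separate arrays 20,897 genes were called, 10,018 higher and 10,879 lower (8,064 and 13,364 with median scaling, 15,911 and 9,799 with normexp background), and the first principal component, with 50.3% of the variance, separated the experiments.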

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

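The tests of array noise, ATF4 targets and RNA without a poly(A) tail below, and the limit of the splits to those that keep paired arrays together, were chosen after the result was seen. Of 110 groups of 4 arrays tested, 3 had an array far from the others. They were RGS16 on control replicate 4 (normalized log2 value -2.16, others -2.39 to -2.37), LIPC on BCAA-free replicate 4 (-5.33, others -5.97 to -5.87, none of them well above background) and DAPL1 on BCAA-free replicate 3 (-3.53, others -5.02 to -4.99). The cut used would flag about 1 in 20 groups of independent values. Each group here holds 2 pairs of similar arrays, so that rate does not apply. Where the experiments differ, the test can hardly find an outlying array.

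For 40 of 51 genes and for 7 lists the effect of BCAA-free medium differed between the experiments by limma or camera on the 8 arrays, a test that measures only the spread between paired arrays. In log2 units, 10-day minus 8-day effect, genes that were higher in BCAA-free cells in both experiments differed by 1.72 (RGS16), 1.97 (PYGO1), 3.47 (PIERCE2), 1.9 (FOXN4), 0.94 (NLGN4X), 1.43 (RASSF8-AS1), 2.11 (ZNF697), 0.44 (RASEF), 0.44 (CCND2), 0.76 (BCAT1) and 1.17 (TRIB3). SESN2 (-1.57) and SLC3A2 (-0.61) were higher at 8 days but hardly differed between media at 10 days (effects of 0.01 and 0.02). Genes lower in both differed by -2.35 (FOS), -1.86 (EGR1), 2.39 (HSPA1A), 1.64 (CASP1), -2.09 (FAM30A), -1.73 (DEPP1), -1.82 (TNF), -2.57 (RAB33A), -0.67 (KHDC3L), -2.39 (PRL), -0.32 (BCKDHA) and -0.68 (CDKN1C). The 15 with opposite signs were DACT1 (4.33), SCN2B (4.2), DAPL1 (4.12), NOX4 (3.97), RARB (-5.58), SNORA2C (-5.12), CRYBA1 (-4.87), CHAC1 (-4.73), DBT (0.6), BCKDK (-0.57), SUZ12 (0.68), ATF4 (-0.24), ASNS (-1.78), SLC7A5 (-0.91) and MYC (1.71). PIERCE2, ZNF697, HSPA1A, CASP1, KHDC3L, PRL, DACT1, SCN2B, DAPL1, NOX4, RARB and CRYBA1 were not well above background in at least 1 of the 4 pairs of arrays, so for them these are measured differences whose true size is not known. Median effects differed by -1.13 for histones, -1.74 for cholesterol genes and 0.91 for MYC and ribosome biogenesis genes. They differed by -0.61 for immediate early genes (adjusted p = 0.121 with an estimated correlation), -0.58 for G2/M genes (0.052), 0.07 for endoplasmic reticulum chaperones (0.597) and 0.48 for T-cell leukaemia transcription factors (0.173).

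The median difference of the effects was 7.1 times the size that the spread between duplicate arrays gives, but this sets single cultures against that spread and decides nothing on the cause. One candidate explanation is that the 10-day controls had already started the amino acid response: their ATF4 targets lay a median of 0.52 above those of the 8-day BCAA-free cells (25 genes, random lists of like brightness -0.34 to 0.19). Another is more RNA without a poly(A) tail in the 10-day controls, since the effect on small nucleolar, Cajal body and spliceosomal RNAs differed by a median of -0.75 (254 genes, random lists -0.27 to -0.06). For protein-coding genes other than histones it would give 1 shared shift, while 14 of 40 lists lay outside the range of random lists of like brightness, 2 above and 12 below. At least 3 on either side were asked for to argue against it in general. MYC and ribosome biogenesis genes lay above their range (0.86, random lists -0.06 to 0.36, 38 genes higher and 2 lower). Cholesterol genes lay below theirs (-1.39, random lists -0.14 to 0.46, 23 genes lower and 1 higher). A single shift cannot give both, which argues against this explanation for these lists. For the other genes both explanations stay open. So does a true difference between 8 and 10 days, because each experiment is 1 culture per medium and day.

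Paired arrays count as 1 sample, so 3 splits of the 8 arrays into 4 and 4 keep each pair together, too few for a share under 0.05. The split by medium called 1,291 genes (highest other 7,890, no other term in the model), and 2 of the 3 called at least as many. The larger was the split by experiment, which points to a structure of the samples. For the split by experiment, 1 of the 3, the real one, called 7,890 (highest other 1,291).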

How the results depend on the processing

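Chosen after the data were seen were the prior that follows the spread between duplicates, the common floor, the filter without spots with outlier flags, the count without histone genes and small non-coding RNAs, set tests on averaged values and the count of genes at least 2-fold away in both experiments. With averaged duplicates, the medium called 979 genes and the experiment 1,344, against 17,854 and 20,897 on separate arrays. The averaged fit has fewer samples and no interaction term, so the difference between the experiments' effects enters its residual. For the medium this count was 0 with normexp background, 0 with quantile normalization, 103 with median scaling, 0 with no filter on dim probes, 0 with a common floor and 542 at an adjusted p under 0.01 (limma, 2,833, 3,529, 9,157 and 2,639 at an unadjusted p under 0.05 for the counts of 0), and 220 to 1,474 with 1 array left out. For the experiment it was 0 with normexp, quantile, median scaling, no filter and the common floor (limma, 6,745, 5,522, 6,009, 5,376 and 4,862 at an unadjusted p under 0.05), 711 with the deposited table, 2,093 over genes well above background on all 8 arrays, 3,131 with trend and robust priors, 3,010 with the prior that follows the duplicates, 265 at an adjusted p under 0.01 and 1 to 2,246 with 1 array left out. The estimated prior degrees of freedom were 18.7 as reported and 0.7 to 5.4 under normexp, quantile, median scaling, no filter and the common floor. On separate arrays the medium called 1,291 genes without an experiment term, 1,912 with the replicate block and 2 with the pair as a random block, and the experiment 7,890 without a treatment term and 1,628 with that random block. With at least 1 log2 unit required, the counts were 2,185 (medium), 2,398 (8 days), 4,659 (10 days), 5,242 (difference of the effects) and 3,673 (experiment), and 9,715 at 8 days with an adjusted p under 0.01. Genes at least 2-fold away in both experiments numbered 271 with normexp. Lists called were 3 with an estimated correlation, 36 with fry, 14 on averaged values, and 0 on averaged values with an estimated correlation or with fry. Beyond the calls given with their results, the replicate block changed no other call of a list, and of named genes it ended no other call. Directions changed for values that were not called (adjusted p of the list tests): fry gave 0.137 for dioxygenases, 0.44 for ribosomal proteins, 0.0792 for lysosome genes and 0.29 for stromal markers, and 0.937 for ribosomal proteins on averaged values. BCAA catabolism gave 0.939 with the replicate block and 0.732 after quantile normalization, which gave 0.981 for mTORC1 genes and 0.697 for serine enzymes. Averaged values gave 0.918 and 0.969 for these, and 0.978 each with an estimated correlation. With 1 array left out, some directions of uncalled lists changed within the ranges for dioxygenases (0.858 to 0.998), BCAA catabolism (0.86 to 1), serine enzymes (0.831 to 1), ribosomal proteins (0.647 to 0.989) and T-cell leukaemia factors (0.813 to 0.998). DBT gave 0.01 with normexp and -0.03 to 0.01 with 1 array left out, and BCL2A1 -0.02 as the mean of its probes. Of the 54 genes followed in the main comparison, 14 were not called on separate arrays without an experiment term, and trend and robust priors ended the call of BMP2 alone (adjusted p = 0.224). The cause was not tested. Where 1 array of a pair is left out, the lone array is assumed to vary like the others. Signal over background limits dim genes on the BCAA-free side. A slide block was not run because there is 1 slide.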

Other observations

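Both tests on immediate early genes were chosen after the result was seen, and both tests on genes measured on few arrays before. Small nucleolar, small Cajal body and spliceosomal RNAs (254 genes) had median log2 effects of BCAA-free medium of 0.19 at 8 days and -0.61 at 10 days. Between 8 and 10 days they differed by a median of 0.44 in control cells and -0.23 in BCAA-free cells.

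Immediate early genes were lower in BCAA-free cells in both experiments. Dim probes on the noisier side of the slide are argued against, since 90% of the members that fell (9 of 10) were well above background on all 8 arrays. Handling or sorting stress in the control cells could also raise these genes, and of 12 heat shock genes other than HSPA1A and HSPA1B, 0 were called lower by limma on averaged arrays, with medians of -0.38 and -0.33. Stress and a response to BCAA cannot be told apart, because the heat shock genes lay below 0 without passing the test and no array of unsorted cells was analysed here.

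Among genes well above background on exactly 2 arrays, rises outnumbered falls (163 and 5 on averaged arrays). A technical origin may account for part of this: of 171 such genes with both arrays BCAA-free, called or not, 38.6% had them in 1 duplicate pair (66 genes, exact Clopper-Pearson interval 31.3 to 46.3), against 33.3% by chance. The 163 rises were not tested on their own. Probes well above background on no array also lay a median of 1.02 log2 units higher on the BCAA-free side (11,424 probes, 1.15 and 1.18 within the experiments). A true rise of some of these genes was not tested separately and stays open.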
